A study of Mus musculus with 7 samples.

How the data were processed

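RNA of sorted mouse thymocytes was hybridised to 7 Agilent 2-colour arrays. Per the labels, each array compared DN4 cells of KN6 γδ T cell receptor transgenic Rag2-/- mice, called Lig+ (4 arrays) or Lig- (3 arrays), with DN3 cells of Rag2-/- mice that lacked the transgene. Cells were sorted by flow cytometry, RNA was isolated with a column kit and amplified with amino allyl nucleotides, and the samples were labelled with Alexa 555 or Alexa 647, per the labels' protocols. The series text calls the arrays biological replicates with 1 dye swap in each group. On the first array of each group the DN4 RNA carried Alexa 647, and on the others Alexa 555. Whether a group's dye swap array used the RNA of another is not stated. Each array counted as 1 sample, and shared RNA would lower n and may leave p too small. Groups came from source names, which name DN4 on slides 1 and 2 only. Replicate numbers follow the order of the samples and only name them, and replicates 1, 2 and 3 of both groups lay on slides 1, 2 and 3. Whether the DN3 RNA was one pool or several preparations is not stated, and neither is how Lig- cells came to lack the ligand.

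The scanner files hold spot intensity values that were extracted with Agilent Feature Extraction, per the file headers. The headers give version 9.5.1.1 for slides 1 and 2 and 9.5.3.1 for slides 3 and 4, and the submitters' notes 9.5.1.1 alone. The authors' deposited series table holds log10 ratios of DN4 over DN3, as a comparison with Agilent's log ratio in each scanner file showed (largest difference 4.87e-08), with a median of 0 in every column. Slides 1 and 2 were scanned on one day and slides 3 and 4 on another, per the file headers. Slide 4 held 1 Lig+ array alone.

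Mean spot signals and median local backgrounds were read with R 4.3.3 (data.table package, version 1.17.8) and analysed with limma 3.58.1. Background was corrected by normexp with an offset of 50, and each array was normalised by loess with the 1639 control spots at a weight of 0. Control spots were then left out, spots marked as outliers by the scanner software (0.354% of spots) were set missing, and spots of one probe were averaged. Of 41174 probes, 34889 were well above background in either channel on at least 3 arrays and were kept. The median signal per array ran from 233 to 595 in the DN4 channel and from 443 to 571 in the DN3 channel, and 0 spots were saturated. Probes were named through their accession (22951), a current symbol (6653) or an older symbol (3102) in a RefSeq gene table of the mouse, and 8468 kept the name in the file. For a gene with several probes the one with the highest mean intensity over the arrays was used, which left 23593 genes, of which 16954 had a gene symbol. The probes of some genes disagreed, and in Lig+ against DN3 those of H2-K1, Slc2a3, Col1a1 and Pfkp differed in sign (-0.97 to 0.62, -0.033 to 1.20, -0.032 to 0.89 and -0.52 to 2.13). For Pfkp the probes of either sign passed the threshold.

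Before the ratios were turned to DN4 over DN3, Agilent's log ratios correlated across probes at 0.556 to 0.910 between arrays of one orientation and at -0.841 to -0.496 between arrays of opposite orientation, which checks the dye labels. Log2 ratios of all 7 arrays, turned to DN4 over DN3, were fitted with limma (lmFit and eBayes) with a term for Lig+, a term for Lig- and a dye term, with Benjamini-Hochberg adjustment over 23593 genes at a threshold of 0.05. The fit had 4 residual degrees of freedom and 2.33 prior ones. The dye term was needed because each group held 1 array of one orientation, and it passed the threshold in 283 genes. The ratio to DN3 was tested against 0, and the difference of the groups as a contrast. The median SE was 0.0866 for Lig+ against DN3, 0.0948 for Lig- against DN3 and 0.122 between the groups. No named gene lay below background on every array of a group.

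Gene lists numbered 28, with 21 of pathways or stages and 7 of markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and compares them with no other genes. Lists, groups, the fit, most alternatives and the rule for named genes were set before the data were examined. The rule took, for each comparison, the 10 largest rises and the 10 largest falls among named genes past the threshold with a log2 change of at least 1 and one direction on every array. It added 2 to 4 members of each list, those past the threshold with the largest change or, where none passed, those with the smallest p, and all probes for γ or δ receptor genes and Rag2. Some genes that this rule took are not reported here and do not enter the counts of named genes. Sex-linked genes were listed as a check of the mice. The fits within each scan day, the fit with scan day as a fixed term, the list of innate lymphoid type 3 markers and the count of other chromosome windows were chosen after seeing the data.

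Alternatives changed one choice at a time, except that Agilent's processed signals came with median centring in place of loess, the authors' values replaced all steps before the fit, the fit of scan day 2 alone had no dye term since all its arrays had one orientation, and slide as a fixed block took the place of the dye term, which does not vary within a slide. They were no background subtraction, Agilent's processed signals, median centring, quantile scaling of the mean intensity, no filter or a stricter filter on dim probes, no dye term, slide or scan day as a block, the mean of a gene's probes, trended and robust moderation, array weights, the arrays of one group alone, the first 2 arrays of each group averaged, the authors' values, a minimum log2 change, and each array left out in turn. Without replicate 1 of either group the contrast is the same, since the dye term takes up the other Alexa 647 array. Unchanged groups were simulated 100 times to set the correlation and the overlap of the comparisons beside chance. The steps were tested on simulated data of 23593 genes with known changes. For Lig+ against DN3 the fit recovered 43 of 67 at 1.5-fold, 57 of 67 at 2-fold and 66 of 66 at 4-fold, and called 10 unchanged genes. For Lig- against DN3 it recovered 41, 58 and 65 of as many and called 8 unchanged genes. For Lig+ against Lig- it recovered 9, 42 and 62 and called 5. No changed gene was called in the wrong direction, and a shifted list of 22 genes was called in each comparison with 0 other lists. The real residuals correlated within slides (0.591), so these counts give no error rate for the arrays. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.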

Results

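Gene expression was measured in thymocytes of KN6 T cell receptor transgenic Rag2-/- mice. KN6 is a γδ T cell receptor known to recognise the class I-like proteins encoded by H2-T10 and H2-T22, which pair with B2m. The labels name 3 flow-sorted populations: transgenic DN4 cells called Lig+ or Lig-, and DN3 cells of Rag2-/- mice without the transgene. Source names of scan day 2 omit DN4. DN3 and DN4 are consecutive stages of thymocytes without CD4 or CD8. Each 2-colour Agilent array held RNA of 1 DN4 sample in one channel and DN3 RNA in the other, for 4 Lig+ and 3 Lig- arrays on 4 slides scanned on 2 days. Each array carried 45018 spots, and the share of probes well above background ran from 72.9% to 84.9% in the DN4 channel and from 75.8% to 83.7% in the DN3 channel. The number of arrays limits the precision. Changes are log2 ratios ± SE from one limma fit of 23593 genes over the 7 arrays, with n = 4 Lig+ and n = 3 Lig- arrays, and the test threshold was an adjusted p of 0.05. DN3 entered as 1 control sample with the ratio tested against 0, which leaves out the spread between DN3 samples. Scan day 2 alone (2 Lig+ and 1 Lig- arrays of the same orientation) had no dye term and 1 residual degree of freedom. Its values against DN3, list medians included, thus hold any dye effect. Its spread comes from the 2 Lig+ arrays and is assumed for the Lig- array.

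Rag2, which is knocked out in all 3 populations, gave -3.04 ± 0.093 in Lig+ against DN3 and -3.02 ± 0.10 in Lig- against DN3 (limma adjusted p = 8.70e-06 and 1.92e-05). Lig+ and Lig- differed by -0.019 ± 0.13 (adjusted p = 0.955). Whether this probe lies in the deleted part is not known here, so it checks nothing about the labels. Probes for γ receptor genes moved in different directions. The Tcrg-V2 probe rose by 1.38 ± 0.14 in Lig+ and 2.00 ± 0.15 in Lig- cells. The Tcrg probe A_52_P200125 rose by 2.74 ± 0.15 and 2.68 ± 0.16, whereas the Tcrg probe A_51_P354616 fell, with log2 changes of -1.54 ± 0.29 and -1.99 ± 0.32. These calls were lost without Lig+ replicate 1 and without Lig- replicate 1, in that order (adjusted p 1.98e-05 to 0.107 and 1.59e-05 to 0.0786 over the alternatives). The Tcrg probe A_51_P429241 gave -0.22 ± 0.12 and 0.027 ± 0.13, and the Tcrg-C probe A_51_P285256 gave 0.022 ± 0.22 and -0.0044 ± 0.28, without passing the test. The Tcrg probe A_51_P429241 had a dye coefficient of 1.57, with array ratios of 1.41 and 1.54 on the Alexa 647 arrays and of -1.94 to -1.23 on the others. It passed below 0 in both groups within each scan day, at -0.23 and -0.13 on day 1 (adjusted p = 0.00473 and 0.0333) and at -1.77 and -1.23 on day 2 without a dye term (1.49e-04 and 0.00385). None of these 5 probes passed it between Lig+ and Lig- (limma adjusted p from 0.102 upward), although the Tcrg-V2 probe did with slide as a fixed block (-0.72, adjusted p = 0.00650, against 9.79e-04 to 0.312 over the alternatives). The Y-linked gene Eif2s3y ranged from -6.54 to 1.64 over the Lig+ arrays and from -2.13 to 0.11 over the Lig- arrays.

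The first comparison asked how DN4 cells that carry the KN6 receptor in the Lig+ setting differed from DN3 cells without it. The early growth response genes, which T cell receptor signals induce, stood among the largest rises: Egr1 (6.71 ± 0.24), Egr3 (6.70 ± 0.15) and Egr2 (6.09 ± 0.14). S1pr1, the receptor that guides cells out of the thymus, rose as well (5.99 ± 0.44), with its regulator Klf2 (5.82 ± 0.46) and Gimap3 (6.16 ± 0.45) and Gimap4 (5.49 ± 0.56). The other large rises were St6gal1 (5.90 ± 0.38), Myo6 (5.51 ± 0.32) and Cxcr6 (5.34 ± 0.38). Genes of the pre-TCR stage fell, including Il2ra, the CD25 chain that marks DN3 cells (-5.29 ± 0.20), Ptcra, the pre-TCR alpha chain (-5.22 ± 0.26), and Dntt, which adds bases at receptor joints (-5.00 ± 0.42). Tifa (-5.62 ± 0.36), Tox3 (-5.58 ± 0.37), Mpzl2 (-5.55 ± 0.16), Bst1 (-5.40 ± 0.34), Fbp1 (-5.01 ± 0.085), Myl10 (-4.85 ± 0.27) and Zeb2 (-4.63 ± 0.32) completed the 10 largest falls. Limma gave these 20 genes adjusted p of 5.07e-04 or lower, and each had the same direction on 4 of 4 Lig+ arrays. On Lig+ replicate 2 Gimap4 stood at 3.47, against 5.77 to 6.19 on the other Lig+ arrays. Other probes of 5 of these genes lay over 1.5 log2 units closer to 0, at 0.35 for Egr3, 1.14 for Klf2, 0.067 for Myo6, 2.69 for St6gal1 and -1.61 for Zeb2. In all, 8575 genes passed, of which 4110 rose and 4465 fell, and 2611 of them changed by at least 1 on the log2 scale.

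Among genes that T cell receptor signals induce, 19 of 22 measured genes rose and 3 fell (19 and 3 adjusted over the list alone), among them Nr4a1 (4.85 ± 0.23). The receptor signal list had a median of 3.41 (3.17 on day 1 and 3.34 on day 2), with a camera adjusted p = 1.58e-09 and an adjusted p = 0.162 with an estimated correlation. Of the genes of the CD3 complex and proximal receptor signalling, 10 of 17 measured genes rose and 4 fell (11 and 5 adjusted over the list alone), among them Txk (4.28 ± 0.19), Cd6 (3.93 ± 0.12) and Zap70 (2.90 ± 0.059). Camera gave the CD3 list an adjusted p = 0.00336, and an adjusted p = 0.187 with an estimated correlation, at a median of 0.53 (0.44 on day 1 and 0.69 on day 2). That call was lost on scan day 2 alone (adjusted p 0.00165 to 0.0826 over 16 settings). Among NF-kappaB targets, 8 of 12 measured genes rose and 1 fell (9 and 3 adjusted over the list alone), among them Bcl3 (3.45 ± 0.15) and Relb (2.72 ± 0.11). The NF-kappaB list had a median of 1.29 (1.29 on day 1 and 1.28 on day 2), with a camera adjusted p = 0.00148 and an adjusted p = 0.237 with an estimated correlation. For costimulatory and inhibitory receptors, 12 of 17 measured genes rose and 1 fell (12 and 2 adjusted over the list alone), among them Btla (4.69 ± 0.28), Ctla4 (-4.48 ± 0.67) and Pdcd1 (3.55 ± 0.36). Camera gave the costimulation list an adjusted p = 8.82e-05, and an adjusted p = 0.237 with an estimated correlation, at a median of 1.30 (1.02 on day 1 and 1.81 on day 2).

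Of the genes of the cytotoxic and interferon-gamma programme, 18 of 20 measured genes rose and 0 fell (18 and 0 adjusted over the list alone), among them Klrd1 (4.53 ± 0.32), Il2rb (3.84 ± 0.26) and Xcl1 (3.76 ± 0.31). The cytotoxic list had a median of 1.98 (1.58 on day 1 and 2.10 on day 2), with a camera adjusted p = 1.58e-09 and an adjusted p = 0.218 with an estimated correlation. In the gamma-delta lineage and IL-17 programme, 5 of 12 measured genes rose and 1 fell (6 and 1 adjusted over the list alone), among them Etv5 (4.88 ± 0.30) and Cd163l1 (3.86 ± 0.21). Camera gave the γδ and IL-17 list an adjusted p = 0.0466, and an adjusted p = 0.332 with an estimated correlation, at a median of 0.70 (0.90 on day 1 and 0.31 on day 2). Camera no longer called the list without Lig+ replicate 2, without a dye term, on scan day 1 alone, on scan day 2 alone, with scan day as a fixed term and with only probes well above background on every array (adjusted p 0.0157 to 0.106 over 16 settings). Of the innate-like T cell genes, 7 of 11 measured genes rose and 0 fell (8 and 0 adjusted over the list alone), among them Icos (1.92 ± 0.27) and Id2 (1.74 ± 0.12). The innate-like list had a median of 0.74 (0.69 on day 1 and 1.18 on day 2), with a camera adjusted p = 6.25e-04 and an adjusted p = 0.237 with an estimated correlation. Among trafficking receptors and their regulators, 11 of 14 measured genes rose and 1 fell (11 and 1 adjusted over the list alone), among them Itgb7 (5.28 ± 0.31). Camera gave the trafficking list an adjusted p = 2.79e-06, and an adjusted p = 0.237 with an estimated correlation, at a median of 2.92 (3.03 on day 1 and 2.99 on day 2). On Lig+ replicate 2 Itgb7 stood at 4.00, against 5.53 to 5.63 on the other Lig+ arrays. The other Etv5 probe gave 3.04.

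Of the Notch targets and pre-TCR stage genes, 1 of 11 measured genes rose and 9 fell (1 and 9 adjusted over the list alone), among them Rag1 (-4.58 ± 0.25). The Notch and pre-TCR list had a median of -3.49 (-3.28 on day 1 and -4.09 on day 2), with a camera adjusted p = 1.20e-04 and an adjusted p = 0.237 with an estimated correlation. Among early progenitor genes, 0 of 13 measured genes rose and 10 fell (1 and 10 adjusted over the list alone), among them Erg (-4.59 ± 0.19) and Lyl1 (-2.87 ± 0.22). Camera gave the progenitor list an adjusted p = 1.84e-05, and an adjusted p = 0.162 with an estimated correlation, at a median of -1.33 (-1.38 on day 1 and -1.18 on day 2). Of the mitotic genes, 16 of 22 measured genes rose and 0 fell (17 and 0 adjusted over the list alone), among them Cenpa (1.54 ± 0.32) and Birc5 (1.18 ± 0.29). The mitotic list had a median of 0.83 (0.59 on day 1 and 1.37 on day 2), with a camera adjusted p = 6.88e-05 and an adjusted p = 0.546 with an estimated correlation. Among p53 targets, 8 of 15 measured genes rose and 2 fell (10 and 2 adjusted over the list alone), among them Cdkn1a (-3.14 ± 0.10) and Zmat3 (2.00 ± 0.17). Camera gave the p53 list an adjusted p = 0.0154, and an adjusted p = 0.218 with an estimated correlation, at a median of 0.32 (0.34 on day 1 and 0.38 on day 2). Cdkn1a, a cell cycle inhibitor, went against the direction of the list. Probes ranged from -5.71 to -2.94 for Rag1 and from -4.59 to -2.39 for Erg. Cenpa lost this call without Lig+ replicate 1 (adjusted p 8.76e-06 to 0.134 over the alternatives). Birc5 lost this call without Lig+ replicate 1, 3 or 4 (adjusted p 2.59e-04 to 0.225 over the alternatives).

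Of the ribosome biogenesis genes, 1 of 22 measured genes rose and 16 fell (1 and 18 adjusted over the list alone), among them Wdr12 (-1.34 ± 0.10) and Gnl3 (-1.30 ± 0.071). The ribosome list had a median of -0.53 (-0.45 on day 1 and -0.78 on day 2), with a camera adjusted p = 3.22e-06 and an adjusted p = 0.303 with an estimated correlation. Among cholesterol synthesis genes, 0 of 19 measured genes rose and 9 fell (0 and 9 adjusted over the list alone), among them Dhcr7 (-1.57 ± 0.067). Camera gave the cholesterol list an adjusted p = 0.00336, and an adjusted p = 0.523 with an estimated correlation, at a median of -0.41 (-0.33 on day 1 and -0.47 on day 2). Of the glycolysis genes, 10 of 18 measured genes rose and 4 fell (10 and 4 adjusted over the list alone), among them Pfkp (2.01 ± 0.15) and Eno1 (1.86 ± 0.28). The glycolysis list had a median of 0.44 (0.43 on day 1 and 0.17 on day 2), with a camera adjusted p = 0.0466 and an adjusted p = 0.303 with an estimated correlation. The list was not called without Lig+ replicate 1 or 2 or Lig- replicate 2, with Agilent's processed signals, with median centring, without a dye term, on scan day 1 alone, on scan day 2 alone, with scan day as a fixed term and with only probes well above background on every array (adjusted p 0.0329 to 0.414 over 16 settings). Probes of Pfkp ranged from -0.52 to 2.13. The other pathway lists did not pass. Their medians were 0.27 (camera adjusted p = 0.168) for double-positive thymocyte genes, -0.14 (camera adjusted p = 0.103) for DNA replication, 0.34 (camera adjusted p = 0.339) for interferon response, -0.48 (camera adjusted p = 0.339) for heat shock, and 0.35 (camera adjusted p = 0.548) for MHC class I genes, which lay at 0.33 on day 1 and -0.49 on day 2. The BCL2 family list had a median of 0.21 (camera adjusted p = 0.339) and a mean of -0.062, of the other sign. Single members of these lists passed, such as Cd2 (4.16 ± 0.40), Bmf (-3.98 ± 0.17), Ccne1 (1.58 ± 0.15) and Oasl2 (-2.71 ± 0.37). Probes of Bmf ranged from -3.98 to -0.39. On Lig+ replicate 2 Cd2 stood at 2.59, against 4.43 to 4.56 on the other Lig+ arrays.

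Markers of other cell types moved beside these groups. Of the macrophage and monocyte markers, 2 of 13 measured genes rose and 9 fell (2 and 10 adjusted over the list alone), among them Ctss (3.79 ± 0.10) and Lyz2 (-3.05 ± 0.36). Camera gave the macrophage list an adjusted p = 0.0496, and an adjusted p = 0.633 with an estimated correlation, at a median of -1.33 (-1.62 on day 1 and -0.64 on day 2). The list lost its call without Lig+ replicate 1, 2 or 4 or Lig- replicate 2 or 3, with Agilent's processed signals, on scan day 2 alone, with scan day as a fixed term and with only probes well above background on every array (adjusted p 0.00134 to 0.414 over 16 settings). On Lig+ replicate 2 Ctss stood at 3.54, against 3.88 to 3.93 on the other Lig+ arrays. Among granulocyte markers, 0 of 10 measured genes rose and 5 fell (0 and 7 adjusted over the list alone), among them S100a8 (-1.16 ± 0.31) and Ngp (-1.04 ± 0.083). The granulocyte list had a median of -0.53 (-0.45 on day 1 and -0.45 on day 2), with a camera adjusted p = 0.00148 and an adjusted p = 0.187 with an estimated correlation. The remaining marker lists did not pass, with medians of -0.024 (camera adjusted p = 0.281) for B cells, -0.39 (camera adjusted p = 0.387) for erythroid cells, 0.016 (camera adjusted p = 0.453) for dendritic cells and MHC class II, -0.67 (camera adjusted p = 0.152) for NK and innate lymphoid cells, and -0.094 (camera adjusted p = 0.211) for thymic epithelium and stroma. Within them, Ccr9 (3.21 ± 0.12) rose, and Epcam (-3.70 ± 0.16), Cldn4 (-3.04 ± 0.19) and Igll1 (-2.66 ± 0.41) fell, with another Igll1 probe at -0.10. All 17 lists past the threshold had the same sign of the median on both scan days, and camera passed 0 of the 28 lists with an estimated correlation (6 at an unadjusted p under 0.05). Fry called 18 lists and, of those camera called, left out the mitotic and macrophage lists (fry adjusted p = 0.0666 and 0.765). S100a8 lost this call without Lig+ replicate 1, 3 or 4 or Lig- replicate 1, with Agilent's processed signals, with its own arrays alone and with the authors' values (adjusted p 5.57e-05 to 0.167 over the alternatives). Igll1 lost this call without Lig+ replicate 1 (adjusted p 2.65e-05 to 0.0781 over the alternatives).

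The count of 8575 genes depended on the only Lig+ array with DN4 RNA in Alexa 647: without Lig+ replicate 1 it was 4005. With slide or scan day as a random block 7762 and 7072 genes passed, and with scan day as a fixed term 11287. Day 1 alone gave 14399 genes and day 2 alone 10930, each with 1 residual degree of freedom. Of 118 named genes that passed, 114 had one direction on all 4 Lig+ arrays, which their selection favours.

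The second comparison set Lig- DN4 cells against the same DN3 population. Cd163l1, also called Scart1 and expressed by IL-17-producing γδ T cells, rose (5.34 ± 0.23), together with the γδ lineage factor Etv5 (5.66 ± 0.33). The other large rises were Tktl1 (6.44 ± 0.38), St6gal1 (6.41 ± 0.42), Myo6 (6.11 ± 0.35), Gem (5.95 ± 0.29), Slc15a1 (5.88 ± 0.56), Iqch (5.65 ± 0.26) and Tdrp (5.56 ± 0.32). Il2ra fell here too (-5.45 ± 0.22). The largest falls were Khdc1a (-7.58 ± 0.62) and Ifi202b (-6.62 ± 0.60), followed by Mpzl2 (-5.41 ± 0.18), Bst1 (-5.21 ± 0.37), Fbp1 (-5.16 ± 0.093), Rhoj (-4.85 ± 0.14), Ndrg1 (-4.77 ± 0.24), Rab38 (-4.76 ± 0.088) and Scel (-4.74 ± 0.085). For these 19 genes limma gave adjusted p of 5.01e-04 or lower, with one direction on 3 of 3 Lig- arrays. Other probes of 7 of these genes lay over 1.5 log2 units closer to 0, at 0.54 for Myo6, 2.87 for Iqch, 3.40 for St6gal1, 3.73 for Etv5, -4.07 for Khdc1a, -3.95 for Il2ra and -3.10 for Rhoj. In all, 7380 genes passed, with 3843 higher and 3537 lower than in DN3 cells, and 2327 changed by at least 1 on the log2 scale.

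In the gamma-delta lineage and IL-17 programme, 11 of 12 measured genes rose and 0 fell (11 and 0 adjusted over the list alone), among them 5830411N06Rik (4.27 ± 0.24). Camera gave the γδ and IL-17 list an adjusted p = 1.02e-08, and an adjusted p = 0.124 with an estimated correlation, at a median of 3.75 (3.64 on day 1 and 3.59 on day 2). Among genes that T cell receptor signals induce, 15 of 22 measured genes rose and 3 fell (15 and 3 adjusted over the list alone), among them Egr1 (4.23 ± 0.26) and Dusp6 (4.17 ± 0.12). The receptor signal list had a median of 1.22 (1.26 on day 1 and 0.83 on day 2), with a camera adjusted p = 1.48e-04 and an adjusted p = 0.254 with an estimated correlation. Of the CD3 and proximal signalling genes, 10 of 17 measured genes rose and 3 fell (10 and 4 adjusted over the list alone), among them Txk (4.20 ± 0.21) and Zap70 (3.01 ± 0.064). Camera gave the CD3 list an adjusted p = 0.00390, and an adjusted p = 0.254 with an estimated correlation, at a median of 0.91 (0.99 on day 1 and 0.55 on day 2). For NF-kappaB targets, 7 of 12 measured genes rose and 3 fell (7 and 3 adjusted over the list alone), among them Bcl3 (2.02 ± 0.16) and Relb (1.97 ± 0.12). The NF-kappaB list had a median of 0.64 (0.69 on day 1 and 0.64 on day 2), with a camera adjusted p = 0.0181 and an adjusted p = 0.370 with an estimated correlation. That call was lost on scan day 1 alone (adjusted p 0.00488 to 0.115 over 16 settings). Among trafficking receptors and their regulators, 11 of 14 measured genes rose and 1 fell (11 and 1 adjusted over the list alone), among them S1pr1 (5.22 ± 0.48) and Klf2 (5.15 ± 0.51). Camera gave the trafficking list an adjusted p = 6.31e-06, and an adjusted p = 0.281 with an estimated correlation, at a median of 3.64 (3.41 on day 1 and 3.86 on day 2). Of the double-positive thymocyte genes, 10 of 17 measured genes rose and 4 fell (11 and 4 adjusted over the list alone), among them Ccr9 (4.26 ± 0.14) and Cd2 (3.83 ± 0.44). The double-positive list had a median of 0.94 (0.91 on day 1 and 0.90 on day 2), with a camera adjusted p = 0.00680 and an adjusted p = 0.254 with an estimated correlation. The other Klf2 probe gave 0.62.

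Of the Notch targets and pre-TCR stage genes, 0 of 11 measured genes rose and 11 fell (0 and 11 adjusted over the list alone), among them Ptcra (-4.70 ± 0.28) and Nrarp (-3.93 ± 0.20). Camera gave the Notch and pre-TCR list an adjusted p = 9.13e-08, and an adjusted p = 0.254 with an estimated correlation, at a median of -2.18 (-2.28 on day 1 and -3.10 on day 2). Early progenitor genes moved alike, where 1 of 13 measured genes rose and 10 fell (1 and 10 adjusted over the list alone), among them Erg (-3.50 ± 0.21) and Bcl11a (-2.58 ± 0.27). The progenitor list had a median of -1.23 (-1.24 on day 1 and -1.04 on day 2), with a camera adjusted p = 4.90e-06 and an adjusted p = 0.124 with an estimated correlation. Of the DNA replication genes, 1 of 25 measured genes rose and 8 fell (1 and 10 adjusted over the list alone), among them Tk1 (-0.99 ± 0.16) and Mcm3 (-0.98 ± 0.12). Camera gave the replication list an adjusted p = 1.96e-04, and an adjusted p = 0.428 with an estimated correlation, at a median of -0.39 (-0.57 on day 1 and 0.053 on day 2). Camera no longer called the list on scan day 2 alone (adjusted p 4.94e-07 to 0.914 over 16 settings). Among ribosome biogenesis genes, 0 of 22 measured genes rose and 12 fell (0 and 13 adjusted over the list alone), among them Wdr12 (-0.95 ± 0.11) and Nop16 (-0.92 ± 0.074). The ribosome list had a median of -0.37 (-0.35 on day 1 and -0.52 on day 2), with a camera adjusted p = 1.28e-05 and an adjusted p = 0.370 with an estimated correlation. Cholesterol synthesis genes followed, where 0 of 19 measured genes rose and 14 fell (0 and 14 adjusted over the list alone), among them Idi1 (-1.96 ± 0.16) and Stard4 (-1.91 ± 0.21). Camera gave the cholesterol list an adjusted p = 1.21e-06, and an adjusted p = 0.330 with an estimated correlation, at a median of -1.01 (-1.06 on day 1 and -1.0 on day 2). Of the glycolysis genes, 9 of 18 measured genes rose and 2 fell (9 and 2 adjusted over the list alone), among them Slc2a3 (2.00 ± 0.11) and Slc16a3 (1.30 ± 0.079). The glycolysis list had a median of 0.49 (0.45 on day 1 and 0.27 on day 2), with a camera adjusted p = 0.00465 and an adjusted p = 0.254 with an estimated correlation. Other probes gave -0.92 for Bcl11a and 0.021 for Slc2a3. Tk1 lost this call without Lig- replicate 1 and on scan day 2 alone (adjusted p 4.67e-05 to 0.0890 over the alternatives). Mcm3 lost this call without Lig- replicate 1 (adjusted p 8.54e-05 to 0.0529 over the alternatives).

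Among MHC class I and antigen processing genes, 0 of 13 measured genes rose and 4 fell (0 and 4 adjusted over the list alone), among them B2m (-4.29 ± 0.28) and Psmb9 (-0.78 ± 0.15). Camera gave the class I list an adjusted p = 0.00390, and an adjusted p = 0.428 with an estimated correlation, at a median of -0.43 (-0.38 on day 1 and -0.90 on day 2). Of the interferon response genes, 1 of 22 measured genes rose and 12 fell (2 and 12 adjusted over the list alone), among them Ifi44 (-2.27 ± 0.35) and Ifih1 (-2.12 ± 0.17). The interferon list had a median of -0.56 (-0.74 on day 1 and -0.035 on day 2), with a camera adjusted p = 0.00339 and an adjusted p = 0.428 with an estimated correlation. The list was not called on scan day 2 alone (adjusted p 3.20e-05 to 0.497 over 16 settings). For heat shock and stress genes, 1 of 13 measured genes rose and 5 fell (1 and 7 adjusted over the list alone), among them Hspa1a (-3.09 ± 0.50) and Hspa8 (-1.13 ± 0.12). Camera gave the heat shock list an adjusted p = 0.0433, and an adjusted p = 0.428 with an estimated correlation, at a median of -0.53 (-0.60 on day 1 and -0.29 on day 2). The list lost its call without Lig- replicate 1 or 2, without a dye term, on scan day 2 alone, with scan day as a fixed term and with only probes well above background on every array (adjusted p 0.00310 to 0.296 over 16 settings). The B2m probes gave -4.29, -4.22 and -0.57. Pathway lists that did not pass had medians of 0.70 (camera adjusted p = 0.116) for innate-like T cell genes, 0.12 (camera adjusted p = 0.184) for p53 targets, 0.18 (camera adjusted p = 0.0542) for the BCL2 family, and 0.30 (camera adjusted p = 0.200) for costimulatory and inhibitory receptors. The mitotic list lay at 0.088 (camera adjusted p = 0.592), with -0.21 on day 1 and 1.08 on day 2. The cytotoxic list had a median of -0.18 (camera adjusted p = 0.531) but a mean of 0.33, and camera and fry pointed up. Members that passed included Gzma (4.58 ± 0.36), Icos (3.62 ± 0.30), Cdkn1a (-3.64 ± 0.11), Bbc3 (1.82 ± 0.16) and Pdcd1 (3.92 ± 0.39). Psmb9 lost this call without Lig- replicate 1 and with arrays 1 and 2 of each group averaged (adjusted p 1.72e-04 to 0.166 over the alternatives). Ifi44 and Hspa1a lost these calls without Lig- replicate 1 (adjusted p 1.90e-04 to 0.0913 and 1.61e-05 to 0.0688 over the alternatives).

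Of the macrophage and monocyte markers, 1 of 13 measured genes rose and 11 fell (1 and 11 adjusted over the list alone), among them Lyz2 (-2.96 ± 0.39) and Ctss (2.27 ± 0.10). The macrophage list had a median of -1.21 (-1.12 on day 1 and -1.14 on day 2), with a camera adjusted p = 0.00198 and an adjusted p = 0.428 with an estimated correlation. The other marker lists did not pass, with medians of 0.29 (camera adjusted p = 0.321) for B cells, -0.22 (camera adjusted p = 0.229) for erythroid cells, -0.25 (camera adjusted p = 0.0542) for granulocytes, -0.57 (camera adjusted p = 0.232) for NK and innate lymphoid cells, and -0.22 (camera adjusted p = 0.136) for thymic epithelium and stroma. The dendritic cell and MHC class II list had a median of -0.69 (camera adjusted p = 0.184), whereas fry pointed up. H2-Ab1, an MHC class II chain, fell (-2.07 ± 0.20), as did Cldn4 (-2.94 ± 0.21) and Epcam (-2.45 ± 0.17). Medians of 15 of the 16 lists past the threshold kept their sign on both scan days, and DNA replication was the exception. Camera passed 0 of the 28 lists with an estimated correlation (5 at an unadjusted p under 0.05), while fry called 21 and, of those camera called, left out the heat shock and macrophage lists (fry adjusted p = 0.110 and 0.0604).

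Without Lig- replicate 1, the array with DN4 RNA in Alexa 647, the count of 7380 genes was 2734. With slide or scan day as a random block 6772 and 5835 genes passed, with scan day as a fixed term 9605, on day 1 alone 14274 and on day 2 alone, which held 1 Lig- array, 6568. Of 112 named genes that passed, 111 had one direction on all 3 Lig- arrays, which their selection favours.

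**Figure D1:**
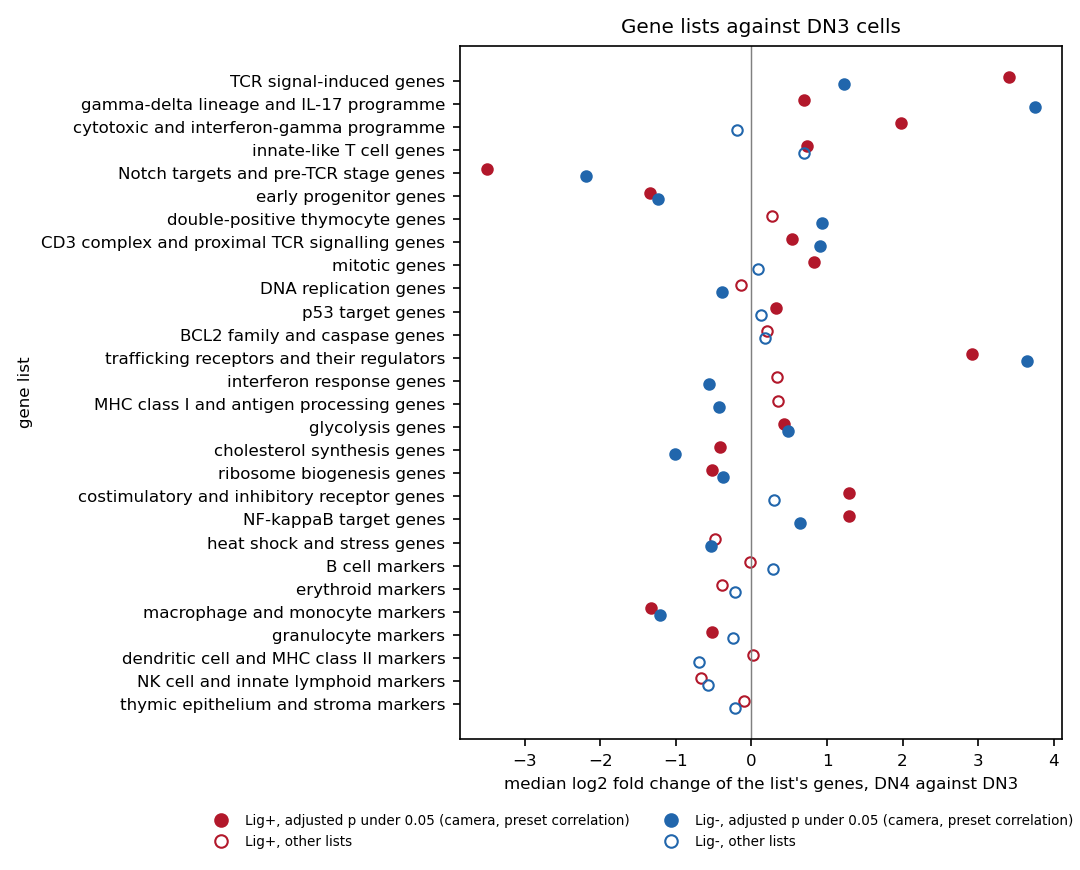
Median log2 change of each of the 28 gene lists against DN3 (horizontal axis), for Lig+ (red) and Lig- (blue) DN4 cells, with filled points for lists past the camera threshold with the preset correlation. The gamma-delta lineage and IL-17 programme lies at 0.70 in Lig+ and 3.75 in Lig- cells, and the T cell receptor signal-induced genes at 3.41 and 1.22.

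The changes against DN3 were compared between the 2 DN4 populations. Il2ra, Mpzl2, Bst1 and Fbp1 stood among the 10 largest falls of both, and St6gal1 and Myo6 among the 10 largest rises of both. Genes that rose in both numbered 2345 and genes that fell in both 2576, and a further 326 passed in opposite directions. Independent calls would give 669, 669 and 1343, but the comparisons are not independent. In 100 simulations of unchanged groups on these slides with the same dye term, at most 1 gene was called in both, and lists of the real sizes taken by p shared a mean of 1891 rises, 1900 falls and 221 genes in opposite directions. Neither value holds both the real effects and the shared parts, so the excess over them is no measure of a shared effect. Across the 23593 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.746, and 100 further simulations of that kind gave a mean r of 0.585. The covariance was 0.413 against a simulated 0.0113, a difference of 0.402. The DN3 control could not be split and its own deviation was in no simulation, so part of the excess may come from the shared control. Arrays of one group scanned on one day correlated at 0.915 to 0.953, arrays of one group on different days at 0.768 to 0.864, arrays of different groups on one day at 0.680 to 0.754, and the others at 0.542 to 0.701.

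The third comparison asked what distinguished the Lig+ from the Lig- DN4 cells, with the limma contrast of their ratios to DN3 (Lig+ minus Lig-). Lig+ cells had more Egr3 and Egr2, which T cell receptor signals induce (5.89 ± 0.21 and 4.70 ± 0.20), more B2m, the light chain of class I molecules (5.14 ± 0.37), and more of the effector genes Xcl1 (5.02 ± 0.44), Klrd1 (4.82 ± 0.45) and Crtam (4.28 ± 0.61). Pdxdc1 (4.58 ± 0.44), Aim2 (4.46 ± 0.41) and Dapl1 (4.36 ± 0.88) and the MHC class II chain H2-Ea (4.12 ± 0.50) were also higher. Lig- cells had more Il17re, an interleukin receptor of the IL-17 family (-4.57 ± 0.13). Esm1 (-4.50 ± 0.88), Nebl (-4.19 ± 0.41), Ankrd6 (-4.14 ± 0.15), Prodh (-4.10 ± 0.54), Iqch (-3.92 ± 0.33), Tdrkh (-3.91 ± 0.14), Osbpl1a (-3.84 ± 0.21) and Sdc4 (-3.75 ± 0.31) were lower in Lig+ than in Lig- cells. For these 19 genes the adjusted p was 0.0267 or lower, and the 4 Lig+ arrays lay all above or all below the 3 Lig- arrays, as their selection required. On Lig+ replicate 3 Esm1 stood at -4.59, against -1.50 to -0.97 on the other Lig+ arrays. Of the 100 tested genes nearest to B2m in chromosome order, 22 differed as well, against 13.2% of the other genes. Other probes of 5 of these genes lay over 1.5 log2 units closer to 0, at 0.43 for Egr3, 1.09 for B2m, 0.30 for Pdxdc1, -2.03 for Nebl and -0.033 for Osbpl1a. In all, 2776 genes differed, with 1134 higher and 1642 lower in Lig+ cells, and 1153 of them by at least 1 on the log2 scale. Egr3 lost this call with only probes well above background on every array (adjusted p 1.73e-05 to 0.108 over the alternatives). Dapl1 lost this call without Lig+ replicate 1, 3 or 4 or Lig- replicate 1 or 2, with Agilent's processed signals and with the authors' values (adjusted p 6.47e-04 to 0.137 over the alternatives). Esm1 lost this call without Lig+ replicate 1 or Lig- replicate 1, 2 or 3, with arrays 1 and 2 of each group averaged and on scan day 2 alone (adjusted p 2.62e-04 to 0.106 over the alternatives).

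**Figure D2:**
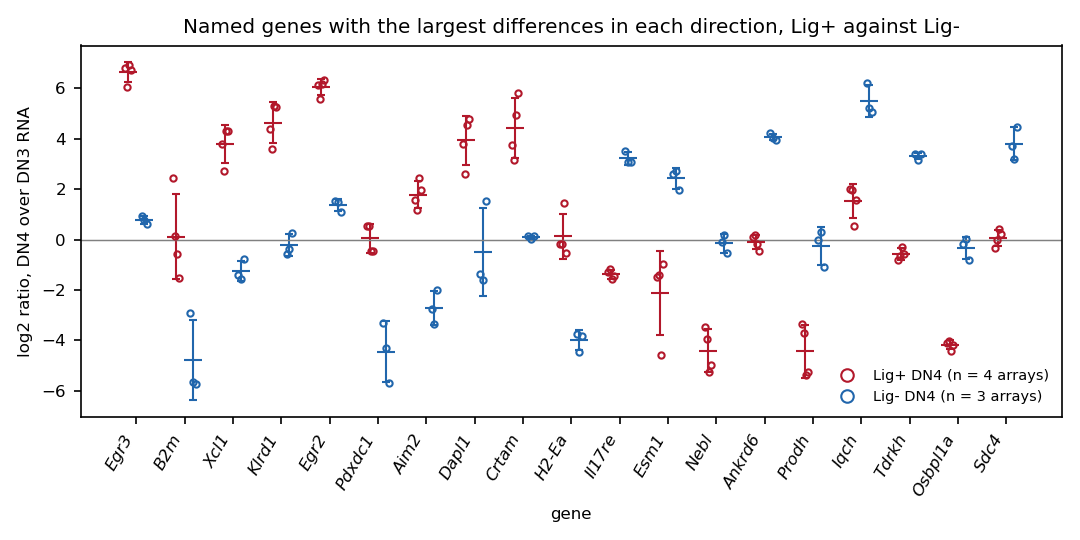
Log2 ratio of DN4 over DN3 RNA (vertical axis) for the named genes with the largest differences in each direction (10 higher and 9 lower in Lig+ cells), with each array as an open circle (4 Lig+ in red, 3 Lig- in blue) and the group mean with 1 SD as a bar. For each gene the Lig+ arrays lie all above or all below the Lig- arrays, as for Egr3 with a difference of 5.89 and Il17re with -4.57.

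Among genes that T cell receptor signals induce, 12 of 22 measured genes were higher in Lig+ cells and 0 were lower (16 and 2 adjusted over the list alone), among them Tnfrsf9 (3.95 ± 0.46) and Irf4 (3.15 ± 0.21). Camera gave the receptor signal list an adjusted p = 3.44e-09, and an adjusted p = 0.163 with an estimated correlation, at a median of 1.19 (1.57, 1.14 and 1.09 on slides 1, 2 and 3). In the cytotoxic and interferon-gamma programme, 15 of 20 measured genes were higher in Lig+ cells and 2 were lower (15 and 2 adjusted over the list alone), among them Cxcr3 (3.85 ± 0.25) and Ccl5 (3.43 ± 0.47). The cytotoxic list had a median of 1.51 (1.48, 1.28 and 2.00 on slides 1, 2 and 3), with a camera adjusted p = 1.17e-08 and an adjusted p = 0.468 with an estimated correlation. Of the gamma-delta lineage and IL-17 genes, 0 of 12 measured genes were higher in Lig+ cells and 7 were lower (0 and 9 adjusted over the list alone), among them Sox13 (-3.37 ± 0.41) and Maf (-2.57 ± 0.14). Camera gave the γδ and IL-17 list an adjusted p = 3.55e-08, and an adjusted p = 0.163 with an estimated correlation, at a median of -1.73 (-2.11, -1.25 and -2.10 on slides 1, 2 and 3). For costimulatory and inhibitory receptors, 7 of 17 measured genes were higher in Lig+ cells and 2 were lower (8 and 2 adjusted over the list alone), among them Cd83 (2.73 ± 0.31) and Cd28 (2.62 ± 0.12). The costimulation list had a median of 0.49 (0.62, 0.63 and 0.39 on slides 1, 2 and 3), with a camera adjusted p = 0.00555 and an adjusted p = 0.550 with an estimated correlation. Among NF-kappaB targets, 4 of 12 measured genes were higher in Lig+ cells and 1 was lower (5 and 1 adjusted over the list alone), among them Bcl3 (1.43 ± 0.21). Camera gave the NF-kappaB list an adjusted p = 0.0207, and an adjusted p = 0.550 with an estimated correlation, at a median of 0.36 (0.57, 0.40 and 0.32 on slides 1, 2 and 3). That call was lost without Lig+ replicate 1 or Lig- replicate 1 and on scan day 2 alone (adjusted p 0.00335 to 0.140 over 17 settings). With slide as a fixed block, 7 NF-kappaB targets were higher. Other probes gave 0.051 for Tnfrsf9, -0.74 for Cd28 and -4.12 for Maf. Bcl3 lost this call without Lig+ replicate 1 or Lig- replicate 1 or 2 (adjusted p 5.86e-04 to 0.0674 over the alternatives).

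Of the interferon response genes, 8 of 22 measured genes were higher in Lig+ cells and 0 were lower (16 and 0 adjusted over the list alone), among them Mx2 (1.99 ± 0.20) and Oas2 (1.94 ± 0.40). The interferon list had a median of 0.70 (0.81, 1.01 and 0.56 on slides 1, 2 and 3), with a camera adjusted p = 6.20e-07 and an adjusted p = 0.541 with an estimated correlation. Among MHC class I and antigen processing genes, 4 of 13 measured genes were higher in Lig+ cells and 0 were lower (6 and 1 adjusted over the list alone), among them H2-T23 (1.06 ± 0.25) and H2-Q7 (0.80 ± 0.19). Camera gave the class I list an adjusted p = 0.00116, and an adjusted p = 0.550 with an estimated correlation, at a median of 0.50 (0.73, 0.52 and 0.45 on slides 1, 2 and 3). Camera no longer called the list on scan day 2 alone (adjusted p 2.22e-06 to 0.102 over 17 settings). Cholesterol synthesis genes differed too, where 6 of 19 measured genes were higher in Lig+ cells and 0 were lower (8 and 0 adjusted over the list alone), among them Cyp51 (1.59 ± 0.28) and Stard4 (1.30 ± 0.27). The cholesterol list had a median of 0.53 (0.58, 0.78 and 0.68 on slides 1, 2 and 3), with a camera adjusted p = 5.50e-05 and an adjusted p = 0.550 with an estimated correlation. On Lig+ replicate 3 Cyp51 stood at 0.71, against -0.32 to -0.28 on the other Lig+ arrays. Of the DNA replication genes, 1 of 25 measured genes was higher in Lig+ cells and 1 was lower (1 and 1 adjusted over the list alone), namely Mcm3 (1.08 ± 0.16) and Mcm7 (-0.59 ± 0.13). Camera gave the replication list an adjusted p = 0.0194, and an adjusted p = 0.746 with an estimated correlation, at a median of 0.29 (0.41, 0.36 and 0.11 on slides 1, 2 and 3). The list was not called without Lig+ replicate 1 or Lig- replicate 1 or 2 and on scan day 2 alone (adjusted p 9.23e-07 to 0.851 over 17 settings). Of the mitotic genes, each taken at its brightest probe, 0 of 22 measured genes were higher in Lig+ cells and 0 were lower (0 and 0 adjusted over the list alone). The mitotic list had a median of 0.74 (0.79, 0.79 and 0.49 on slides 1, 2 and 3), with a camera adjusted p = 2.80e-05 and an adjusted p = 0.708 with an estimated correlation. At an unadjusted limma p under 0.05, 7 of the 22 mitotic genes passed. With slide as a fixed block 20 of the 22 were higher and 0 lower in Lig+ cells, and 16, 5 and 16 were higher with slide or scan day as a random block and with scan day as a fixed term. Cenpa gave 1.35 ± 0.46 (limma adjusted p = 0.122), and with slide as a fixed block it passed (1.22, adjusted p = 0.00356, against 7.64e-04 to 0.369 over the alternatives). Hmmr gave 1.27 ± 0.45 (adjusted p = 0.135) and passed with that block (adjusted p = 0.00797, against 7.21e-04 to 0.403 over the alternatives). A dimmer probe of Cenpa passed without a block (0.69 ± 0.12, adjusted p = 0.0164), as 1 of the 34 mitotic probes. Of the double-positive thymocyte genes, 1 of 17 measured genes was higher in Lig+ cells and 5 were lower (2 and 7 adjusted over the list alone), among them Aqp11 (-2.95 ± 0.31) and Arpp21 (-2.63 ± 0.18). Camera gave the double-positive list an adjusted p = 0.0456, and an adjusted p = 0.541 with an estimated correlation, at a median of -0.51 (-0.51, -0.42 and -0.56 on slides 1, 2 and 3). The list lost its call without Lig+ replicate 1, 2 or 4 or Lig- replicate 1 or 3, with Agilent's processed signals, without a dye term, with slide as a fixed block and with only probes well above background on every array (adjusted p 0.0102 to 0.124 over 17 settings). With slide as a fixed block, 16 interferon, 9 class I, 13 cholesterol and 11 replication genes were higher in Lig+ cells, and 8 double-positive genes were lower. Oas2 lost this call without Lig+ replicate 1, 3 or 4 or Lig- replicate 1 or 2 and with arrays 1 and 2 of each group averaged (adjusted p 2.62e-04 to 0.145 over the alternatives). H2-T23 lost this call without Lig+ replicate 1, 2 or 3 or Lig- replicate 1, 2 or 3, without a dye term and on scan day 2 alone (adjusted p 7.91e-04 to 0.348 over the alternatives). H2-Q7 lost this call without Lig+ replicate 1, 2 or 3 or Lig- replicate 1, 2 or 3, with Agilent's processed signals, with arrays 1 and 2 of each group averaged, with median centring, without a dye term and on scan day 2 alone (adjusted p 0.00350 to 0.400 over the alternatives). Cyp51 lost this call without Lig+ replicate 1 or Lig- replicate 1 or 2 and on scan day 2 alone (adjusted p 3.90e-04 to 0.0891 over the alternatives). Stard4 lost this call without Lig+ replicate 1, 3 or 4 or Lig- replicate 1 or 2, with arrays 1 and 2 of each group averaged and on scan day 2 alone (adjusted p 3.80e-04 to 0.153 over the alternatives). Mcm3 lost this call without Lig+ replicate 1 or Lig- replicate 1 (adjusted p 6.08e-04 to 0.0718 over the alternatives). Mcm7 lost this call without Lig+ replicate 1 or 3 or Lig- replicate 1, 2 or 3, with median centring and without a dye term (adjusted p 0.00389 to 0.269 over the alternatives).

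Pathway lists that did not differ past the threshold had medians of -0.035 (camera adjusted p = 0.616) for early progenitor genes, -0.11 (camera adjusted p = 0.849) for CD3 and proximal signalling, 0.077 (camera adjusted p = 0.625) for p53 targets, -0.31 (camera adjusted p = 0.204) for the BCL2 family, -0.13 (camera adjusted p = 0.120) for ribosome biogenesis and 0.49 (camera adjusted p = 0.312) for heat shock. Members of some lists went both ways: Id2, a regulator of innate-like lymphocytes, was higher in Lig+ cells (3.72 ± 0.18) and Gata3 lower (-2.69 ± 0.24) within the innate-like list, which had a median of -0.057 (camera adjusted p = 0.821), a mean of 0.15 and fry pointing up. In the Notch and pre-TCR list Dntt was lower (-3.48 ± 0.59) and Nrarp higher (3.03 ± 0.26), with a median of -0.52 (camera adjusted p = 0.915) while camera and fry pointed up. The glycolysis list had a median of 0.040 (camera adjusted p = 0.915) and a mean of -0.012, and camera and fry pointed down. Trafficking receptors had a median of 0.49 (camera adjusted p = 0.900), whereas fry pointed down. Bmf, a pro-apoptotic BCL2 family member, was lower in Lig+ cells (-3.22 ± 0.24), with its probes at -3.22 to -0.19. Dntt lost this call without Lig+ replicate 1 or Lig- replicate 1, 2 or 3 and without a dye term (adjusted p 7.05e-04 to 0.132 over the alternatives).

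Of the B cell markers, 0 of 10 measured genes were higher in Lig+ cells and 3 were lower (0 and 4 adjusted over the list alone), among them Blnk (-1.90 ± 0.29) and Vpreb1 (-1.07 ± 0.12). The B cell list had a median of -0.68 (-0.92, -0.88 and -0.035 on slides 1, 2 and 3), with a camera adjusted p = 0.00474 and an adjusted p = 0.553 with an estimated correlation. That call was lost on scan day 2 alone (adjusted p 1.58e-06 to 0.668 over 17 settings). Among granulocyte markers, 0 of 10 measured genes were higher in Lig+ cells and 1 was lower (0 and 1 adjusted over the list alone), namely Ngp (-0.56 ± 0.12). Camera gave the granulocyte list an adjusted p = 0.0439, and an adjusted p = 0.492 with an estimated correlation, at a median of -0.28 (-0.29, -0.25 and -0.29 on slides 1, 2 and 3). Camera no longer called the list without Lig+ replicate 1 or 4 or Lig- replicate 1 or 3, with Agilent's processed signals and with median centring (adjusted p 0.0201 to 0.0882 over 17 settings). With slide as a fixed block 4 granulocyte markers were lower. The other marker lists did not differ past the threshold, with medians of 0.21 (camera adjusted p = 0.0507) for macrophages and monocytes, a list called in 8 of 17 settings, 0.58 (camera adjusted p = 0.121) for dendritic cells and MHC class II, and -0.079 (camera adjusted p = 0.900) for NK and innate lymphoid cells. The erythroid list had a median of -0.10 (camera adjusted p = 0.915) while camera and fry pointed up, and thymic epithelium and stroma had 0.10 (camera adjusted p = 0.915) while fry pointed down. H2-Ab1 was higher in Lig+ cells (2.83 ± 0.25), as was Ctss (1.52 ± 0.14). All 13 lists past the threshold had one sign on the 3 slides that held both groups, and 12 on both scan days. The exception was the B cell list, at -0.90 on day 1 and 0.016 on day 2. Camera passed 0 of the 28 with an estimated correlation (2 at an unadjusted p under 0.05), and fry called 10. Among the lists that camera called, fry left out the mitotic, DNA replication, class I and cholesterol lists (fry adjusted p = 0.267, 0.394, 0.0653 and 0.0865). Blnk lost this call without Lig+ replicate 1 or Lig- replicate 1 or 2 (adjusted p 2.62e-04 to 0.0642 over the alternatives). Ngp lost this call without Lig+ replicate 1, 3 or 4 or Lig- replicate 1 or 2, with Agilent's processed signals, with arrays 1 and 2 of each group averaged, with median centring, on scan day 2 alone and with the authors' values (adjusted p 0.00160 to 0.165 over the alternatives).

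The count of 2776 genes was 858 without Lig+ replicate 1 or Lig- replicate 1, which give one contrast of 5 arrays. It was 1164 without Lig- replicate 2, 1743 without Lig+ replicate 3 and 1850 without Lig- replicate 3. It was 5268 with slide as a fixed block, 5845 with slide and 4729 with scan day as a random block, 5511 with scan day as a fixed term, 9788 on day 1 alone and 3507 on day 2 alone. Calls given as lost on day 2 alone rest on an arm of 1 Lig- array. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in Lig+ cells on day 1 (-3.98, -4.03, -3.28 and -1.49). Their limma adjusted p of 0.00136 to 0.00619 came from 2 arrays a group that may share RNA. None of the 4 passed on all arrays or with slide as a fixed block. Median centring in place of loess gave 1628 and array weights 5962. In 81 of 86 named genes that passed, no Lig+ array overlapped a Lig- array, which their selection favours, so the 5.71% that chance gives unselected genes is no measure for them.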

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

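The count of other chromosome windows, the innate lymphoid marker test and the fits within each scan day were chosen only after the results were seen. Among 172 reported genes tested for an array far from the other 3 of the Lig+ group, 7 had one, where chance gives about 1 in 20. These are DN4 over DN3 log2 ratios of single arrays. Gimap4 stood at 3.47, Cd2 at 2.59, Itgb7 at 4.00 and Ctss at 3.54 on Lig+ replicate 2, each below the other Lig+ arrays, which started at 5.77, 4.43, 5.53 and 3.88. Cxcl10 stood at 1.03 on Lig+ replicate 4, against 2.02 to 2.13 on the others. On Lig+ replicate 3, Esm1 stood at -4.59, against -1.50 to -0.97, and Cyp51 at 0.71, against -0.32 to -0.28.

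Of the 326 genes that passed against DN3 in opposite directions, with limma's contrast past the threshold too, 14 were among the reported genes. Genes up in Lig+ and down in Lig- cells, with their log2 changes in that order, were B2m (0.85 and -4.29, difference 5.14), Xcl1 (3.76 and -1.27, difference 5.02), Aim2 (1.74 and -2.73, difference 4.46) and Cxcr3 (3.22 and -0.63, difference 3.85). Id2 (1.74 and -1.98, difference 3.72), H2-Ab1 (0.76 and -2.07, difference 2.83), Cd83 (1.81 and -0.92, difference 2.73), Mx2 (0.81 and -1.19, difference 1.99) and Ubash3a (0.31 and -0.55, difference 0.86) did the same. Genes down in Lig+ and up in Lig- cells were Il17re (-1.30 and 3.27, difference -4.57), Esm1 (-1.97 and 2.53, difference -4.50), Tdrkh (-0.60 and 3.30, difference -3.91), Blnk (-0.83 and 1.07, difference -1.90) and Pfkm (-0.71 and 0.46, difference -1.17). The adjusted p of the difference ran from 1.58e-04 to 0.0243 over the 14 genes. The rise of B2m in Lig+ cells was 0.85, and it was lost without Lig+ replicate 1, 2 or 3 or any Lig- array (highest adjusted p of these 0.351). It was also lost without a dye term (0.12, adjusted p = 0.918), with median centring, with the Lig+ arrays alone, with scan day as a random block and with arrays 1 and 2 averaged. On scan day 2 alone, without a dye term, it turned to -1.05 (adjusted p = 0.0147), and the adjusted p ran from 3.33e-04 to 0.918 over the alternatives. Log2 changes under 1 were also lost, by construction, with a minimum log2 change of 1. The rise of H2-Ab1 was lost without Lig+ replicate 3 or 4, with slide or scan day as a random block and with arrays 1 and 2 averaged (adjusted p 0.00195 to 0.0796). Blnk lost its fall without Lig+ replicate 1, with either random block and with arrays 1 and 2 averaged (4.72e-05 to 0.330). Its rise was lost without Lig- replicate 1 or 2 and with arrays 1 and 2 averaged (3.69e-05 to 0.235). The differences of Blnk and Pfkm were lost without Lig+ replicate 1 or Lig- replicate 1 or 2 (2.62e-04 to 0.0642 and 7.27e-04 to 0.0553). That of Esm1 was lost without Lig+ replicate 1 or any Lig- array, with arrays 1 and 2 averaged and on scan day 2 alone (2.62e-04 to 0.106).

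Lig+ exceeded Lig- cells by 5.14 ± 0.37 in B2m (probes at 5.14 and 5.16, a dimmer probe at 1.09) and 4.12 ± 0.50 in H2-Ea. A shift of all class I genes by 5.14 is argued against. The other 12 listed had a median of 0.479 (bootstrap SE 0.161), where at least 2.57 was needed. A smaller one, as of 0.479, stays open. Variants linked to B2m are in line with the calls among its 100 nearest tested genes, of which 22 differed (8 higher and 14 lower in Lig+) against 13.2% of the others (odds ratio 1.85, 95% interval 1.1 to 3.0, one-sided Fisher's exact p = 0.0108), and 2.97% of all 15859 windows of that size held as many. A different MHC haplotype stays open, since the neighbours of H2-Ea gave an odds ratio of 1.15 whose interval reached 2.02 (one-sided Fisher's exact p = 0.347). That Lig- mice lacked B2m itself to remove the ligand is a candidate neither stated nor tested.

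All 12 measured genes of the γδ lineage and IL-17 list were lower in Lig+ than in Lig- cells on either scan day. Scan day as the cause is argued against by medians of -1.63 on day 1 and -2.01 on day 2, which held 1 Lig- array. Innate lymphoid type 3 cells in the Lig- samples stay open. The median of their 10 markers, 6 of which also stand in another list, was 0.38 (bootstrap SE 0.59) over members that went both ways. Id2 (3.72) and Il7r (2.58), which T cells also regulate, were higher in Lig+ and Kit (-0.54) lower, while Nrp1, Ncr1 and Il1r1 (-1.05, -0.69 and -0.60) and the other 4 markers did not pass. Ligand presence, the difference the groups are named for, stays open with any other difference between the mice, such as sex on day 1, so a biological reading remains a hypothesis.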

How the results depend on the processing

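The fits within each scan day and with scan day as a fixed term were chosen only after the data were seen. No paired analysis was possible by replicate number because the labels give none, but slides 1, 2 and 3 each held 1 array of either group, and pairing by slide as a fixed block gave 5268 genes in Lig+ against Lig-. Among named results it added the calls of Cenpa, Hmmr, Fcer1g and the Tcrg-V2 probe and ended that of Fcgr3, and in camera it kept 12 of the 13 lists, all but the double-positive one. Of 331 named calls, 201 kept their direction and stayed past the threshold in every alternative, 130 lost the call in some and 6 changed direction in some. Over 9044 comparisons of a named result with an alternative, 8366 kept direction and side of the threshold, 598 lost a call, 48 gained one and 32 changed direction. The gained calls were those of Cenpa, Hmmr, Fcer1g, Ncr1, the Tcrg-V2 probe and the Tcrg probe A_51_P354616 in Lig+ against Lig-, of Kif20a, Plk1, Gata1 and Klf1 in Lig- against DN3, and of the Tcrg probe A_51_P429241 in Lig+ against DN3, which in Lig- against DN3 passed with its direction turned on either day alone. Quantile scaling of the mean intensity leaves ratios as they are and tested nothing.

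With a minimum log2 change of 1, 2611, 2327 and 1153 genes passed in Lig+ against DN3, Lig- against DN3 and Lig+ against Lig-, fewer by construction. On scan day 1 alone the fit called 14399, 14274 and 9788 genes with 1 residual degree of freedom. Leaving out 1 array at a time gave 4005 to 8890, 2734 to 8105 and 858 to 3546 genes, and the lowest counts came without replicate 1 of the group tested. With arrays 1 and 2 of each group averaged, as for a technical dye swap, 6875, 6785 and 2817 genes passed. The dye term then differed only between the scan days, so a change of that term is mixed into these counts and into calls lost there. Lig+ against Lig- gave 1628 genes with median centring, 5845 with slide and 4729 with scan day as a random block, 5268 with slide as a fixed block, 5511 with scan day as a fixed term and 5962 with array weights, whose estimation stopped before it converged. All other alternatives stayed within 1.5 times the counts of 8575, 7380 and 2776. The cause was not tested for these differences, apart from those given. In camera with an estimated correlation 0, 0 and 0 lists passed (6, 5 and 2 at an unadjusted p under 0.05), against 17, 16 and 13 with the preset one. Fry called 15, 14 and 9 of these, and 13, 12 and 7 held in camera in every other setting run for lists (12, 11 and 5 in fry as well). Of lists not called, those that passed in some of 16 settings were replication (3), class I (1), dendritic cell (1) and heat shock (1) in Lig+ against DN3 and BCL2 family (5), dendritic cell (2), erythroid (2), granulocyte (6) and mitotic (4) in Lig- against DN3, and in some of 17 settings dendritic cell (2), macrophage (8) and ribosome (2) in Lig+ against Lig-. The correlation of changes of 0.746 ran from 0.719 without Lig+ replicate 2 to 0.761, with 0.721 without Lig- replicate 3.

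Of the 124, 118 and 89 named calls of the comparisons, 28 were lost without Lig+ replicate 1 in Lig+ against DN3, 31 without Lig- replicate 1 in Lig- against DN3, and 45 in Lig+ against Lig- without either of them. Some values changed direction. On scan day 2 alone, with 1 Lig- array, 1 residual degree of freedom and no dye term, since all arrays had one orientation, they were B2m (-1.05), H2-T23 (-0.25), H2-K1 (-0.11), Tcrg-C probe A_51_P285256 (-0.0071), B2m probe A_51_P129012 (-1.05) and B2m probe A_51_P129006 (-0.050) in Lig+ against DN3, Vpreb3 (-0.075) and Tcrg probe A_51_P429241 (-1.23) in Lig- against DN3, Tcrg probe A_52_P200125 (-0.17) in Lig+ against Lig-. Without a dye term on all arrays they were Tcrg-C probe A_51_P285256 (-0.17) in Lig+ against DN3, Tcrg probe A_51_P429241 (-0.50) in Lig- against DN3, Tcrg-C probe A_51_P285256 (-0.17) in Lig+ against Lig-. With arrays 1 and 2 of each group averaged they were Tcrg-C probe A_51_P285256 (-0.33) in Lig+ against DN3, Tcrg probe A_51_P429241 (-0.0035) in Lig- against DN3, Tcrg probe A_52_P200125 (-0.048) in Lig+ against Lig-. Array weights turned Tcrg probe A_51_P429241 (-0.021) in Lig- against DN3, Rag2 (0.032) in Lig+ against Lig-, median centring Tcrg probe A_51_P429241 (-0.10) in Lig- against DN3, scan day 1 alone Tcrg probe A_51_P429241 (-0.13) in Lig- against DN3, Agilent's processed signals Tcrg-C probe A_51_P285256 (-0.0082) in Lig+ against DN3, the authors' values Tcrg-C probe A_51_P285256 (0.0019) in Lig- against DN3, and the mean of all probes H2-K1 (-0.054) in Lig+ against DN3. With 1 array left out at a time, values spanned -0.11 to 0.23 for Tcrg-C probe A_51_P285256 in Lig+ against DN3, -0.13 to 0.15 for Tcrg probe A_51_P429241 in Lig- against DN3, -0.033 to 0.024 for Tcrg-C probe A_51_P285256 in Lig- against DN3, -0.10 to 0.079 for Rag2 in Lig+ against Lig-, -0.13 to 0.29 for Tcrg probe A_52_P200125 in Lig+ against Lig- and -0.10 to 0.23 for Tcrg-C probe A_51_P285256 in Lig+ against Lig-. The cause was not tested. Signal over background limits dim genes, since 72.9% to 84.9% of probes were well above background in the DN4 channel.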

Other observations

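The requirement that arrays of different days share no slide was chosen only after the result was seen, as were the slide comparison, the sex-linked genes within slides and days, the splits kept within slides or days, the day term and the α and β receptor probes. Probes of the α chain gene Tcra rose in both groups against DN3, by 5.50 ± 0.55 and 5.71 ± 0.61 (A_51_P484329), 4.27 ± 0.40 and 4.24 ± 0.44 (A_52_P112591) and 3.00 ± 0.30 and 4.07 ± 0.33 (A_52_P480620) in Lig+ and Lig- cells (limma adjusted p 8.22e-04 or lower). The β chain probes went both ways. Tcrb-J probe A_52_P1078023 fell (-1.65 ± 0.10 and -1.04 ± 0.11) and Tcrb-V13 probe A_51_P478172 rose (0.59 and 0.93, dye coefficient 1.33).

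Sex-linked genes differed between arrays and, on scan day 1, between the groups. Ddx3y lay at -5.27, -6.47, 0.12 and 1.58 on the Lig+ arrays and at -1.87, -1.92 and 0.19 on the Lig- arrays. Xist gave 1.53, 1.62, -1.84 and -6.39 on the Lig+ arrays and 1.21, 1.37 and 0.81 on the Lig- arrays. Within slides 1, 2 and 3, Lig+ minus Lig- was -3.40, -4.56 and -0.073 for Ddx3y, -3.41, -4.64 and 0.36 for Eif2s3y, -2.81, -3.76 and 0.32 for Kdm5d, and -1.10, -1.87 and 0.41 for Uty. On day 1 alone these genes and Xist passed between the groups (Xist at 0.29, limma adjusted p = 0.0152). None of the 5 passed in any comparison over all arrays (limma adjusted p from 0.110 upward). With slide as a fixed block none passed between the groups (from 0.109 upward). Sex thus stays open beside the ligand in Lig+ against Lig-, at least on day 1.

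Arrays scanned on one day resembled each other, and 3760 genes passed for a day term added to the fit (7759 at an unadjusted p under 0.05). The day difference in Lig+ (slide 4 minus slide 2) correlated with that in Lig- (slide 3 minus slide 2) at r = 0.516 across genes, and at 0.563 for slide 3 minus slide 2 in both, which may come from a DN3 preparation or processing step shared by a day. For arrays that shared no slide, r was 0.408, so neither the shared step nor its absence is settled. A slide effect alone is argued against, because the 3 pairs of one group and day lay on different slides (lowest r = 0.915, against up to 0.864 across days), but a slide component stays open, since the residual correlation was 0.591 within slides and 0.445 within days (each slide was scanned on 1 day, so the first holds any day effect too). Scan day and software version cannot be told apart, because each version was used on 1 day, and the mice of the 2 days, whose sex-linked genes differed, are an open biological explanation that was not tested.

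Of the 35 splits of the 7 arrays into 4 and 3, only the real split gave 2776 genes (highest other 406). Chance is excluded at a share of 0.05 only if arrays share no RNA and are exchangeable across slides and days. Splits kept within slides number 8 and those kept within days 18, too few for a share under 0.05 (highest others 2 and 406). The split by scan day gave 272 genes. Turning the signs of the Lig+ arrays (8 ways) or Lig- arrays (4 ways) also gives too few for a share under 0.05. The real signs gave 8575 and 7380 genes in limma. The highest others gave 0 and 0 (2372 and 693 at an unadjusted p under 0.05).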
